A study of Homo sapiens with 8 samples.

How the data were processed

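Total RNA of decidualizing human endometrial stromal cells was profiled on Affymetrix 3′ expression arrays. Per the labels' protocols, cells at 80% confluency were transfected with 40 nM siRNA against C/EBPβ or STAT3 or with a scrambled control, and 24 h later received 1 µM progesterone, 10 nM estradiol and 0.5 mM 8-bromo-cAMP. The siRNA stayed for 24 h more and the hormones for a further 48 h. From each sample 100 ng of RNA was amplified and biotin-labelled. The values deposited by the authors are MAS5 signals, linear intensity values per probe set, made with Affymetrix Expression Console version 1 per the submitters' processing notes. The mean signal without the lowest and highest 2% of probe sets was equal, at 150.0 to 150.1, on all 8 arrays, which shows global scaling of each array, and detection calls were not analysed here. Median signals were 23.0 to 25.0 in the C/EBPβ experiment and 34.4 to 36.1 in the STAT3 experiment, and 39.8% to 46.3% of probe sets lay under a signal of 16. No pair of arrays held identical values.

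Samples were grouped by the siRNA and the experiment named in the labels: 3 arrays with C/EBPβ siRNA, 3 with control siRNA of that experiment, 1 with STAT3 siRNA and 1 with control siRNA of that experiment. The comparisons, tests, gene lists, named-gene rule and all alternatives not marked otherwise were fixed before the data were examined. The labels do not say whether replicates were separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

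Of the 22277 probe sets, the platform annotation listed 20113, of which 19070 had 1 gene symbol and 1043 several, and 2164 were not listed, including control probe sets. By Entrez gene identifier 19052 of those with 1 symbol matched the reference gene table, and no symbol changed. Probe sets with several symbols were not used, so some list members were not analysed here. Genes linked to sex were removed from every table, which left 19033 probe sets of 11939 genes. Each gene was represented by the probe set with the highest mean log2 signal over the 6 arrays of the C/EBPβ experiment, and the 40% of genes with the lowest mean were left out, which left 7163. Signals were analysed as log2(signal + 16). Differences on that scale understate the change of genes with low signals. No further normalization was applied.

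C/EBPβ siRNA was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The 26 gene lists held 700 entries, 630 of them on the array, and 23 lists had at least 5 tested members. Lists were tested with limma's camera at a preset correlation of 0.01, which compares a list with the other genes, with fry and an estimated correlation as alternatives. Each list also has the count of members past the threshold adjusted over all genes and adjusted over the list alone. The STAT3 experiment, with 1 array per group, was described by log2 differences of the same probe sets, by counts of genes at least 2-fold apart, and by the percentile of each list's median among 10000 random lists of the same size, matched on deciles of mean expression. Its counts were set beside those between arrays of the same group and beside the spread of the paired differences, and, added after seeing the data, so were its list medians and percentiles. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

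The text names CEBPB, STAT3, PRL, IGFBP1, CCNE1, CCNE2 and CDK2 in any case. In the C/EBPβ comparison it names the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, and up to 4 passing members per list. For STAT3 it names the 8 largest differences in each direction and up to 3 members of a list described, and for shared genes 6 per direction.

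Both groups of the C/EBPβ experiment carry replicate numbers 1 to 3 in the labels. Whether these pair the arrays was checked before the fits were compared, from the correlation across genes of each array's deviation from its group mean. Arrays with the same number correlated at 0.62, 0.70 and 0.54, and arrays with other numbers at -0.50 to -0.06, so the numbers were taken to pair the arrays. The pairing thus comes from the labels' numbers together with these correlations. The fit without the block remained the main result as fixed beforehand, and blocked values stand beside a result where they change its call or its count.

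The fits were tested on simulated data with the 7163 genes' own means and 200 changed genes, 100 at each of 2 sizes. Without pair effects the spreads were the genes' own within-group SDs. With pair effects the pair means were those observed and the spreads were the moderated values of the blocked fit. These settings follow the blocked fit's own model, so its recovered shares may be too high for the real data. With pair effects as in the C/EBPβ experiment, the fit without block recovered 29% of 2-fold and 91% of 4-fold changes with 0% false calls, and the blocked fit recovered 96% and 100% with 6.67% false calls. Without pair effects the recovered shares were 45% and 81% for the fit without block and 4% and 61% for the blocked fit. A simulated list shifted by 1 on the log2 scale was found by camera, and 1 of 50 unshifted lists passed without adjustment. The simulated genes were drawn independently, while the estimated correlation within the tested lists reached 0.72. The simulation therefore does not show how often camera at the preset correlation passes unshifted lists of correlated genes.

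Alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter and a filter at 60%, the mean of all probe sets of a gene, omission of cross-hybridizing probe sets, each probe set tested separately, an intensity trend in the variance prior, the replicate block, adjusted p thresholds of 0.01 and 0.1, fold limits of 1.5 and 3, the mean of all 4 control arrays for STAT3, and each array left out in turn. Added after seeing the data were omission of both arrays of a replicate number, with and without the block, and the actin and the GAPDH 3′/5′ ratio, each as a covariate.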

Results

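Gene expression was measured in cultured human endometrial stromal cells that were driven to decidualize, the differentiation by which the uterine stroma prepares for implantation. Decidualization was induced with progesterone, estradiol and a cyclic AMP analogue, and the cells carried an siRNA against C/EBPβ, an siRNA against STAT3, or a control siRNA. C/EBPβ is a basic leucine zipper transcription factor and STAT3 is the transcription factor activated by cytokines of the interleukin 6 family. The series held 8 arrays: 3 with C/EBPβ siRNA and 3 with control siRNA in the C/EBPβ experiment, and 1 with STAT3 siRNA and 1 with control siRNA in the STAT3 experiment. Each array gave MAS5 signals of 22277 probe sets, and 7163 genes passed the filter on low signal. The number of arrays limits the precision, and the STAT3 experiment has no replicates.

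The targeted transcripts were examined first. In the C/EBPβ experiment the signal of CEBPB was 3705 ± 314 (SD, n = 3) with control siRNA and 721 ± 198 (SD, n = 3) with C/EBPβ siRNA, which is 19.5% of control. The design of the study treats STAT3 as a target of C/EBPβ, and STAT3 fell as well, from 933 ± 113 to 294 ± 65.3 (SD, n = 3), or 31.5% of control. The other STAT3 probe set lay at 35.3% of control. By limma with Benjamini-Hochberg adjustment, CEBPB fell by 2.37 on the log2 scale (SE 0.23, adjusted p = 0.0063) and STAT3 fell by 1.63 (SE 0.21, adjusted p = 0.014). CEBPB kept its call when any single array was left out, but had an adjusted p of 0.087 without both arrays of number 1 and 0.14 without both of number 3. By single arrays, STAT3 had an adjusted p of 0.052 without control array 1, 0.067 without control array 3 and 0.054 without siRNA array 3. In the STAT3 experiment the STAT3 signal was 760.5 on the control array and 34.1 on the STAT3 siRNA array, 4.5% of control, and the other probe set gave 4.8%. CEBPB stood at 57.7% of control on the STAT3 siRNA array.

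**Figure D1:**
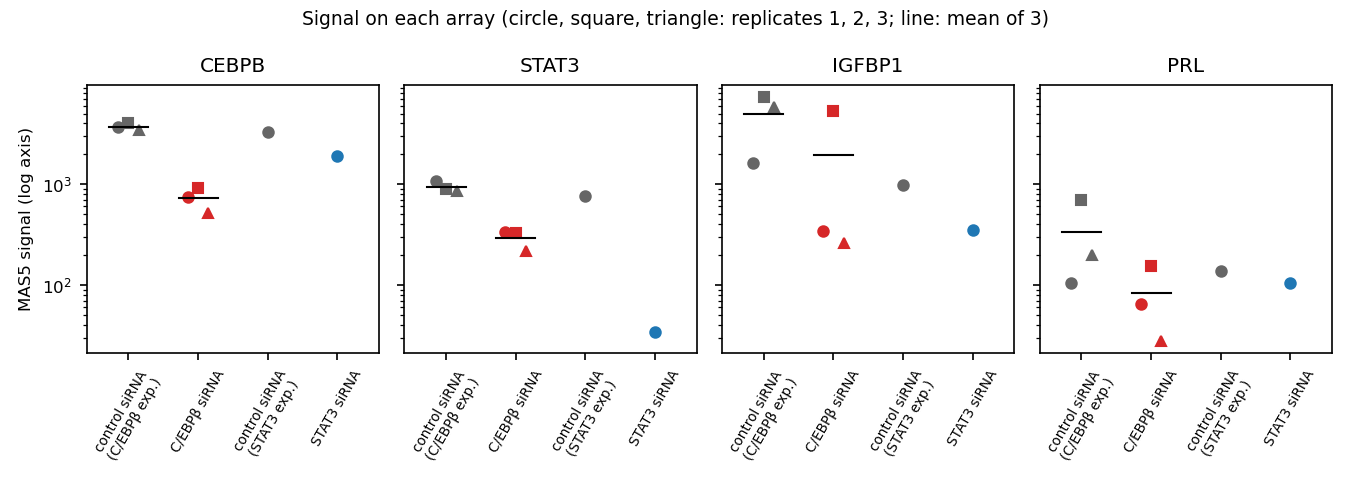
MAS5 signal (log axis) of CEBPB, STAT3, IGFBP1 and PRL on each of the 8 arrays, by group; circles, squares and triangles are replicates 1, 2 and 3, and horizontal lines are means of 3 arrays. All 3 C/EBPβ siRNA arrays lie below all 3 control arrays for CEBPB and STAT3, while the arrays of the 2 groups overlap for IGFBP1 and PRL.

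The comparison of C/EBPβ siRNA with control asked which genes depend on C/EBPβ during decidualization. The steepest rise was that of TNFSF4, the OX40 ligand that costimulates T cells, from a signal of 33.3 ± 12 to 1384 ± 355 (SD, n = 3), a log2 difference of 4.83. ACTC1, cardiac alpha actin, rose by 4.03, CNN1, the actin-binding protein calponin, by 3.78, and ACTG2, smooth muscle gamma actin, by 3.04. Tenascin C (TNC) rose by 3.46 and asporin (ASPN), a small proteoglycan of the matrix, by 3.35. LRRC17 (4.20), the hepatocyte growth factor receptor MET (3.28), the focal adhesion scaffold NEDD9 (3.0) and secretogranin SCG2 (2.76) completed the 10 largest rises.

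The largest fall was that of the chemokine CCL8, from 643 ± 514 to 13.5 ± 11.4 (SD, n = 3), a log2 difference of -4.13. TMEM158 changed by -3.21 and ACKR3, an atypical receptor that binds the chemokine CXCL12, by -2.77. ID4, an inhibitor of helix-loop-helix transcription factors, changed by -2.66 and basigin (BSG) by -2.62. PTGES, which makes prostaglandin E2, fell from 291 ± 36.4 to 39.4 ± 21.5 (SD, n = 3), a log2 difference of -2.55. RGCC (-2.57), the complement protease MASP1 (-2.51), TENT5A (-2.48) and the leucine zipper factor NFIL3 (-2.47) completed the 10 largest falls.

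**Figure D2:**
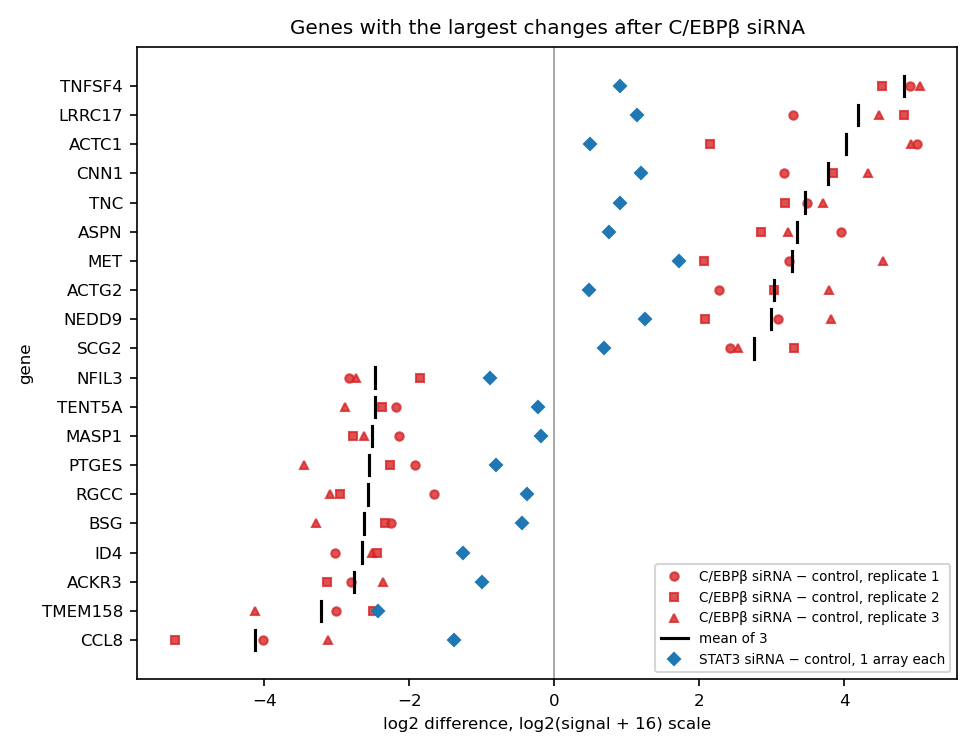
Log2 difference on the log2(signal + 16) scale for the 10 largest rises and 10 largest falls after C/EBPβ siRNA; red symbols are replicates 1 to 3 minus the control array of the same number, black bars are means of 3, and blue diamonds are the single STAT3 siRNA array minus its control. All 3 replicate differences share a sign for each gene by the choice of genes whose groups do not overlap. The diamonds lie on the same side of 0 at smaller sizes.

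By limma's two-sided test on log2(signal + 16), 268 of 7163 genes passed an adjusted p of 0.05, 132 higher and 136 lower, and 195 of them differed at least 2-fold (91 higher, 104 lower). The 3 siRNA arrays lay wholly on one side of the 3 control arrays for 2011 genes, 28.1%. Chance gives 10% if all 6 arrays are exchangeable. In the 3 other splits of the 6 arrays that part all 3 pairs, 164 to 259 genes (2.3% to 3.6%) were so placed. Those splits mix siRNA and control arrays, so genes that respond to the siRNA tend to overlap in them, which lowers these counts. With the replicate number as a block, 1365 genes passed (692 higher, 673 lower), 473 of them at least 2-fold, and all 268 genes were among the 1365. The count without the block was 65 without control array 1, 27 without control array 3, and 118, 83 and 26 without siRNA arrays 1, 2 and 3. Of the 20 genes named above, ACTC1, ACTG2, CCL8, ID4, MASP1 and TENT5A had an adjusted p of 0.051 to 0.085 under at least 1 alternative filter, pseudocount or choice of probe set. With each of the 6 arrays left out in turn, CCL8 passed by limma 2 times, with an adjusted p of up to 0.14. TNFSF4 and CNN1 passed all 6 times.

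Actomyosin and smooth muscle genes rose as a group. Of 20 members tested, 9 rose, 0 fell and 11 did not pass, and the median log2 difference was 0.98. Alpha smooth muscle actin (ACTA2) rose from 760.4 ± 165 to 4089 ± 762 and transgelin (TAGLN) from 629.7 ± 138 to 3198 ± 131 (SD, n = 3), log2 differences of 2.41 and 2.34, beside CNN1 and ACTG2. The group's limma camera test gave an adjusted p of 4.8e-10 with the preset correlation, and adjusted p = 0.078 with an estimated correlation. Adjusted over the list alone 10 members rose, and with the replicate block 14 did. Markers of smooth muscle cells and pericytes, which share CNN1 and ACTG2 with this group, had 2 of 8 members higher (both adjusted over all genes and adjusted over the list alone; 3 with the block, adding MCAM) and a camera adjusted p of 0.089, while probe sets of smooth muscle myosin MYH11 and desmin (DES) had mean signals of at most 10.2 on the siRNA arrays.

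Targets of p53 and apoptosis genes rose too, with 5 of 19 members higher and none lower (camera adjusted p = 0.000101, and adjusted p = 0.38 with an estimated correlation). PMAIP1, which encodes the pro-apoptotic protein NOXA, rose from 206 ± 138 to 1430 ± 890 (SD, n = 3) and TP53I3 from 176 ± 29.4 to 1039 ± 336 (SD, n = 3), log2 differences of 2.75 and 2.41. BAX and BID, both pro-apoptotic members of the BCL2 family, rose by 0.94 and 0.89, and the other riser, the DNA repair gene XPC, by 0.87 (named after its values were seen). PMAIP1 had an adjusted p of 0.049, which passed by little. Under 3 processing alternatives it did not pass (0.051 to 0.091). Adjusted over the list alone 6 members rose and 1 fell, and with the block 11 rose and 1 fell.

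Decidualization markers were lower as a group, with a median log2 difference of -1.29 over 20 members (camera adjusted p = 0.011, and adjusted p = 0.54 with an estimated correlation). WNT4, a signal required for decidualization, fell from 216 ± 86.8 to 40.8 ± 19.1 and the protease inhibitor TIMP3 from 2724 ± 405 to 661 ± 352 (SD, n = 3), log2 differences of -2.02 and -2.16. TIMP3 did not pass under 3 processing alternatives (adjusted p = 0.051 to 0.072), nor WNT4 under 1 (0.054). The other 18 members did not pass, among them the classical markers PRL, with signals of 334 ± 320 and 82.7 ± 64.9, and IGFBP1, with 4938 ± 2960 and 1958 ± 2864 (SD, n = 3). Control signals ranged from 104.9 to 700.1 for PRL and from 1632 to 7344 for IGFBP1. By replicate number, PRL went from 104.9, 700.1 and 197.7 to 65.5, 154.4 and 28.1. IGFBP1 went from 1632, 7344 and 5837 to 345, 5265 and 263. Each pair thus fell, but by very unequal amounts for IGFBP1. By limma the log2 difference of PRL was -1.64 (adjusted p = 0.25, and 0.019 with the replicate block). That of IGFBP1 was -2.35 (adjusted p = 0.29, and 0.049 with the block). With the block 11 markers fell and 4 rose, and adjusted over the list alone 8 fell and 3 rose.

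Among targets of the progesterone and glucocorticoid receptors all 13 members had negative differences, with a median of -0.84 (camera adjusted p = 0.00064, and adjusted p = 0.38 with an estimated correlation). Only KLF4, a zinc finger transcription factor, passed by itself, falling from 110.1 ± 30.7 to 15.9 ± 7.49 (SD, n = 3). Adjusted over the list alone 2 members fell, and with the block 6 did. In the list of STAT3 and interleukin 6 signalling 3 of 28 members fell, and 2 of those were CEBPB and STAT3 themselves, the other being the interleukin 6 receptor IL6R, by 1.00 on the log2 scale (camera adjusted p = 0.0038, and adjusted p = 0.53 with an estimated correlation). CEBPB is the target of the C/EBPβ siRNA, so its fall was set by the design, and the list was not tested without it. IL6R passed by little, at an adjusted p of 0.049. Under 5 processing alternatives it did not pass (0.050 to 0.089). Adjusted over the list alone 4 members fell and 1 rose, and with the block 11 fell and 3 rose.

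Hypoxia and glycolysis genes were lower, and 2 of 22 members passed, the stress-responsive gene NDRG1 with a log2 difference of -2.31 and the glucose transporter SLC2A1 with -1.44 (camera adjusted p = 0.013, and adjusted p = 0.38 with an estimated correlation; adjusted over the list alone 5 fell and 1 rose, with the block 7 fell and 3 rose). Of 12 core histone and related genes 3 fell: H2BC21 by 1.08, H2BC5 by 0.75 and MACROH2A1 by 0.66 (camera adjusted p = 0.000145, and adjusted p = 0.14 with an estimated correlation). H2BC5 did not pass under 1 processing alternative (adjusted p = 0.13) and MACROH2A1 under 5 (0.053 to 0.12). Adjusted over the list alone 8 histone genes fell, as they did with the block. Of 22 endoplasmic reticulum chaperone and folding genes 1 fell, the translocon component SSR1, by 0.77 (camera adjusted p = 0.014, and adjusted p = 0.53 with an estimated correlation; 1 adjusted over the list alone, 5 with the block). SSR1 did not pass under 2 processing alternatives (adjusted p = 0.051 and 0.057). Ribosomal protein genes had a median of -0.11 with no member of 29 past the threshold by limma and 1 at an unadjusted p under 0.05 (none adjusted over the list alone or with the block), and their camera adjusted p of 0.029 became 0.75 with an estimated correlation and 0.38 after quantile normalization. Without control array 2, only 4 of the 9 lists past the camera threshold stayed past it, namely actomyosin genes, p53 targets, progesterone and glucocorticoid receptor targets, and core histones.

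**Figure D3:**
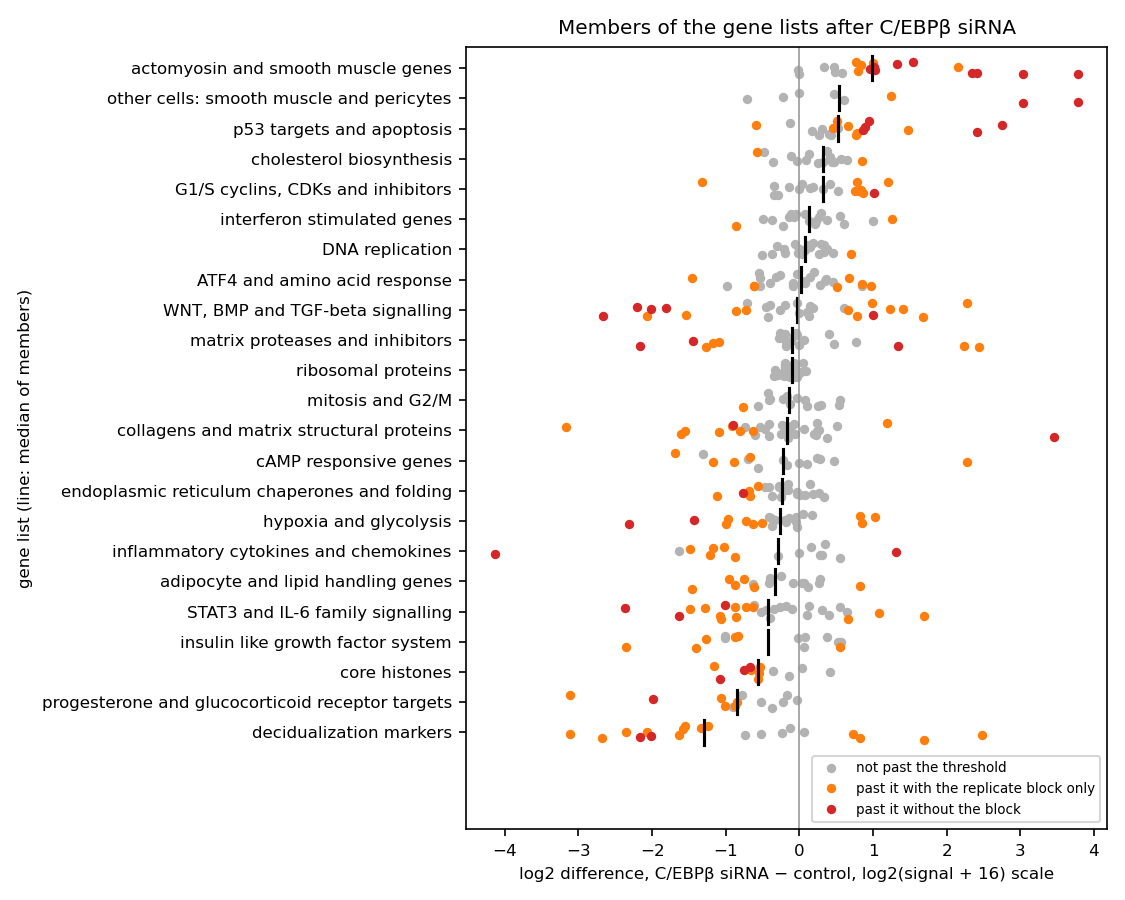
Log2 difference of each member (points) of the 23 tested lists after C/EBPβ siRNA, on the log2(signal + 16) scale; red points passed the threshold without the replicate block, orange points only with it, and black bars are list medians. Actomyosin genes have the highest median, 0.98, and decidualization markers the lowest, -1.29.

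Signalling genes of the WNT, BMP and TGF-beta families moved in both directions, and their camera test did not pass (adjusted p = 0.40). The BMP-responsive gene ID1 fell from 1166 ± 189 to 243 ± 56.4 (SD, n = 3), the WNT antagonist DKK1 fell by 1.81 on the log2 scale, and ID4 and WNT4 fell as given above, while 1 of the 29 members rose, the TGF-beta inhibitor SMAD7, by 1.01 (named after its values were seen). Adjusted over the list alone 4 rose and 6 fell, and with the block 8 did each. In the matrix lists the protease inhibitor SERPINE2 rose by 1.35, and the protease ADAMTS1 and the laminin chain LAMC1 fell by 1.44 and 0.91. Those lists had 1 member higher and 2 lower of 22 proteases and inhibitors (camera adjusted p = 0.41; 2 and 3 adjusted over the list alone, 3 and 5 with the block) and 1 higher and 1 lower of 35 collagens and structural proteins (camera adjusted p = 0.080, and 0.049 with the block, or 0.58 with the block and an estimated correlation; 1 and 2 adjusted over the list alone, 2 and 8 with the block). Inflammatory cytokines had CCL8 lower and TNFAIP6, a hyaluronan-binding protein, higher by 1.32, of 15 members (camera adjusted p = 0.23; the same counts adjusted over the list alone, and 1 higher and 6 lower with the block, adding CCL2, IL1B, NFKBIA, PTGS2 and TNFAIP2).

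Few cell cycle genes passed. Of 19 cyclins, CDKs and inhibitors of the G1/S transition only E2F5 rose, by 1.01 (adjusted p = 0.057 under 1 processing alternative), and the list's camera adjusted p was 0.058, or 0.049 with the block (0.39 with the block and an estimated correlation), where 7 rose and 1 fell; adjusted over the list alone 3 rose. CCNE1, which encodes cyclin E1, had a log2 difference of -0.34 (adjusted p = 0.46) and CDK2 one of 0.04 (adjusted p = 0.92), and both CCNE2 probe sets had mean signals under 16. By limma no member passed among 21 DNA replication genes, 16 mitosis genes, 19 interferon stimulated genes, 15 cAMP responsive genes, 26 genes of the amino acid response, 17 cholesterol synthesis genes, 14 genes of the insulin-like growth factor system or 16 adipocyte and lipid genes. At an unadjusted p under 0.05 those lists had 3, 0, 2, 4, 8, 2, 5 and 5 members, and adjusted over the list alone none did except 1 lower adipocyte gene, CEBPA (log2 difference -1.46), named after its values were seen. Their camera adjusted p values were 0.62, 0.48, 0.55, 0.30, 0.92, 0.36, 0.27 and 0.063, the last 0.049 with the block. With the block and an estimated correlation no list passed camera (lowest adjusted p = 0.39). With the block 1, 1, 2, 5, 7, 2, 6 and 6 of their members passed. Of markers of other cells, none of 4 epithelial and 4 endothelial genes passed, nor at an unadjusted p under 0.05, while with the block KRT18 and FLT1 were higher, and the only immune marker above the filter, CD14, had a log2 difference of -1.84 (adjusted p = 0.078, 0.0032 with the block, and under 0.05 without adjustment, hence also adjusted over the list alone).

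Signal ratios of the 3′ to the 5′ beta-actin control probe sets, which rise as RNA degrades, were 7.98, 3.40 and 3.67 on the control arrays and 6.68, 1.85 and 3.93 on the C/EBPβ siRNA arrays, so they differed more between replicate numbers than between groups. The ratios of the GAPDH control probe sets were 1.55, 1.08 and 1.40 on the control arrays and 1.45, 1.01 and 1.21 on the C/EBPβ siRNA arrays, lower on the siRNA array of each number. In the STAT3 experiment the actin ratios were 1.31 and 1.11 and the GAPDH ratios 1.01 and 1.03. Geometric mean signals of the poly-A spikes were 86.0, 213 and 134 on the control arrays and 73.9, 176 and 92.7 on the C/EBPβ siRNA arrays, lower in each pair. Those of the hybridization spikes were 799.6, 1023 and 1017 against 827, 921.8 and 876.7. In the STAT3 experiment both were lower on the siRNA array, the poly-A spikes at 244 against 546 and the hybridization spikes at 564 against 861. With the GAPDH ratio as a covariate 444 genes passed by limma, and the camera adjusted p was 0.0059 for inflammatory cytokines, 0.016 for cholesterol synthesis and 0.054 for ribosomal proteins. With that covariate and an estimated correlation no list passed (lowest adjusted p = 0.33), and these 3 had 0.61, 0.61 and 0.68.

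The STAT3 experiment asked what the loss of STAT3 does in the same setting, with 1 array against 1 and therefore no test. After STAT3 itself, the most reduced genes on the STAT3 siRNA array were TMEM158 (log2 difference -2.44), CYTL1 (-2.42), the sphingosine kinase SPHK1 (-2.05) and NNMT (-1.99), followed by the kynureninase gene KYNU (-1.84), COL15A1 (-1.83) and CD14 (-1.74). The oxytocin receptor OXTR was the most increased, with signals of 179 and 878 (log2 difference 2.20), followed by MX1 (1.94), SEMA3C (1.82), KRT19 (1.73), NRXN3 (1.73), MET (1.72), GBP1 (1.67) and STC2 (1.66). In all 103 genes differed at least 2-fold, 58 higher and 45 lower. The balance depended on scaling, with 50 higher and 54 lower after median centring and 50 each after quantile normalization. Arrays of the same group in the C/EBPβ experiment differed at least 2-fold in 289 to 637 genes, and the spread of the paired differences there corresponds to 94 to 121 genes for a single pair, so the count does not exceed what unreplicated arrays give.

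Interferon stimulated genes stood out on the STAT3 siRNA array. Their median log2 difference was 0.78 over 19 members, above that of all 10000 random lists matched on expression (median 0.05). MX1 had signals of 18.2 and 115.5, GBP1 91.0 and 324, and ISG15, a ubiquitin-like modifier, 128 and 415, in control and STAT3 siRNA order. In the C/EBPβ comparison the same list had a median of 0.13 and, as given above, no member past the threshold. With the block GBP1 rose by 1.26 (adjusted p = 0.032; groups not overlapping) and IFIT3 fell by 0.86 (adjusted p = 0.045).

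Further lists lay in the outer 5% of random lists, 16 of 23 in all, 4 high and 12 low. Arrays of the same group in the C/EBPβ experiment put 9 to 17 of the 23 lists there, and single paired differences minus the mean of the 3 put 7 to 13. An outer rank alone therefore does not set a list apart. The median of interferon genes was larger in size than in any of these differences (at most 0.64), as were those of actomyosin genes (at most 0.18), hypoxia and glycolysis genes (0.23) and ribosomal proteins (0.13). The other 12 outer lists did not exceed them all. The high ones besides interferon genes were cholesterol synthesis (median 0.31, led by TM7SF2 at 0.80 and HSD17B7 at 0.74), actomyosin genes (0.19, led by CCN2 at 1.55 and CNN1 at 1.19) and p53 targets (0.17, led by PMAIP1 at 1.59). The low ones included decidualization markers, with a median of -0.37 and IL11 at -1.46 and IGFBP1 at -1.43, hypoxia and glycolysis genes (-0.36, VEGFA at -0.97), mitosis genes (-0.34, CDC25B at -0.70), collagens and structural proteins (-0.34, COL15A1 at -1.83), and WNT, BMP and TGF-beta genes (-0.25, TGFBR3 at -1.34). Also low were cAMP responsive genes (-0.28, STC1 at -0.80 but INHBA at 0.82), progesterone and glucocorticoid receptor targets (-0.27, HSD11B1 at -0.99), STAT3 and interleukin 6 signalling (-0.25, with STAT3 itself and OSMR at -1.31), folding genes (-0.21, ERO1A at -0.79), the amino acid response (-0.17, VLDLR at -1.31 but STC2 at 1.66) and lipid genes (-0.15, ABCA1 at -1.04). Ribosomal protein genes were low at -0.29, but at -0.03 after quantile normalization of the array pair. The 7 lists inside the central range were G1/S genes (0.07), DNA replication (0.03, and -0.03 after quantile normalization), inflammatory cytokines (-0.09), matrix proteases (-0.09, and 0.01 after quantile normalization), the insulin-like growth factor system (-0.12), core histones (-0.12) and smooth muscle and pericyte markers (0.07, and -0.12 after quantile normalization). PRL had a log2 difference of -0.35, CCNE1 of -0.63 and CDK2 of 0.21. Of 4 epithelial markers measured, KRT19 was higher by 1.73 and KRT18 by 0.71 on the log2 scale on the STAT3 siRNA array. Arrays of the same group in the C/EBPβ experiment differed by up to 4.04 and 2.39 in these genes, so both lie within that spread. It is a spread between replicate numbers, and the spread of the paired differences was not examined for these genes. The 4 endothelial markers had a median of 0.07.

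The design also asked which genes lie downstream of both factors. Of the 195 genes past the threshold and at least 2-fold after C/EBPβ siRNA, 11 were also at least 2-fold higher and 9 at least 2-fold lower on the STAT3 siRNA array, where independent lists would share 0.74 and 0.65. Shared higher genes included SEMA3C, a secreted semaphorin, with log2 differences of 2.63 and 1.82 after C/EBPβ and STAT3 siRNA, MET (3.28 and 1.72), PMAIP1 (2.75 and 1.59), FILIP1L (1.46 and 1.27), NEDD9 (3.0 and 1.25) and CNN1 (3.78 and 1.19). Shared lower genes included TMEM158 (-3.21 and -2.44), KYNU (-2.14 and -1.84), STAT3 (-1.63 and -3.95), the transcription factor ETS2 (-2.34 and -1.50), CCL8 (-4.13 and -1.38) and ID4 (-2.66 and -1.26). STAT3 is the target of the STAT3 siRNA, so its fall there was set by the design. The 9 shared lower genes include it. In the opposite direction lay 2 genes, where independent lists would share 1.41: TNFAIP6 (1.32 and -1.20) and, named after its values were seen, the acetylcholine receptor subunit CHRNA9 (1.83 and -1.23). Of the 268 genes past the threshold after C/EBPβ siRNA, 216 (80.6%) had the same sign on the STAT3 siRNA array, against 50% to 70.1% for differences between arrays of the same group, each turned to its larger share. Of the 1365 genes past it with the block 1024 (75.0%) did, against 56.2% to 70.9%. ETS2 did not pass under 1 processing alternative (adjusted p = 0.053). CEBPB was lower on the STAT3 siRNA array too (log2 difference -0.79), so the transcripts of both factors were lower in each experiment. The comparisons have separate control arrays. Across all 7163 genes, which are not independent replicates, their differences correlated with Pearson's r of 0.43 and Spearman's rho of 0.35.

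**Figure D4:**
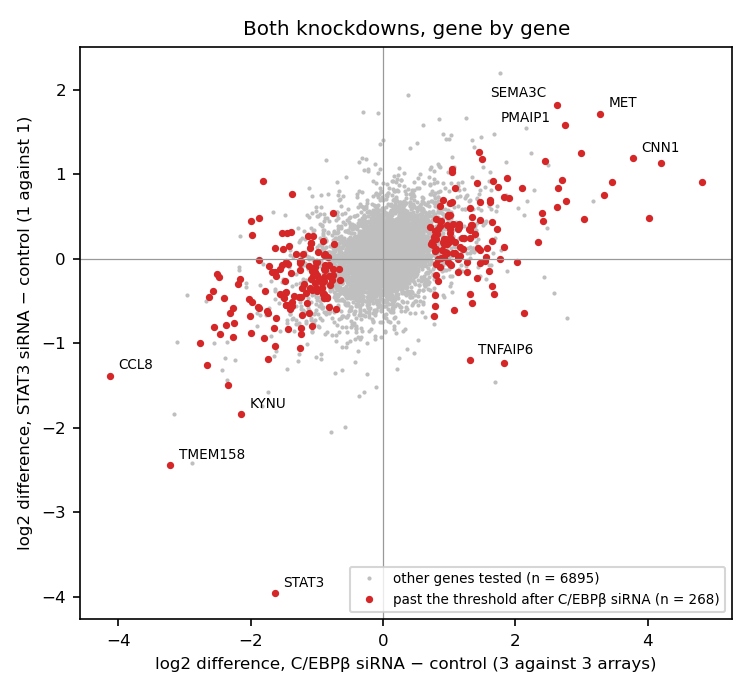
Log2 difference after C/EBPβ siRNA (horizontal axis, 3 against 3 arrays) against log2 difference after STAT3 siRNA (vertical axis, 1 against 1) for 7163 genes, both on the log2(signal + 16) scale; red points passed the threshold after C/EBPβ siRNA. Of the 268 red points, 216 lie in the quadrants of shared sign.

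The 20 shared genes became 50 with the replicate block, and 8, 7, 10 and 5 without control array 1, control array 3, siRNA array 1 and siRNA array 3. With a single pair of arrays in the STAT3 experiment, a shared direction of any 1 gene has no replicate check there.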

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

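The signals below come from probe sets that the comparisons of the report do not use, and the control probe sets were looked up after the interferon genes had been seen. Control probe sets on the array for ISGF3A, named for the transcription complex that interferon activates, were higher on the STAT3 siRNA array than on its control, with a median ratio of 1.70 over 4 probe sets (1.54 to 1.78). On the C/EBPβ siRNA arrays the same probe sets had log2 differences of -0.73 to -0.02. These control probe sets were not matched to a gene here, so they may measure a member of the interferon list. Their ratios also come from the same array pair, so they are no separate evidence for the interferon pattern. Of 663 probe sets above the signal filter that the annotation does not list, 23 passed the limma threshold after C/EBPβ siRNA when tested together with the genes (7 higher, 16 lower), and 115 with the replicate block. Their log2 differences reached 2.83 and -2.27, and their genes are unnamed here.

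Interferon stimulated genes on the STAT3 siRNA array were weighed against array scaling, and, in a test chosen after the result was seen, against the STAT3 level itself. Scaling or compression of bright signals is argued against by quantile normalization, which left the median of the 19 genes at 0.72. A lower STAT3 level as such may raise these genes, but STAT3 also fell after C/EBPβ siRNA, where the mean of the list plus 2 standard errors was 0.37, too wide to exclude a small rise. STAT3 was reduced far more by its own siRNA, so that test leaves the explanation open. A reaction of that culture to its siRNA was not tested, and with 1 array per group it stays open too.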

How the results depend on the processing

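With 268 genes past the threshold after C/EBPβ siRNA, the replicate block gave 1365, an adjusted p threshold of 0.01 gave 21 and 0.1 gave 598. Leaving out arrays gave 0 to 239, where fewer samples are part of the cause: single arrays gave 26 to 239, and in alternatives added after seeing the data, omitting both arrays of a replicate number gave 4 (number 1), 105 (number 2) and 0 (number 3). At an unadjusted p under 0.05 limma gave 1548 genes with all arrays and 1219, 1354 and 759 in those cases. Past the adjusted threshold, the paired fit gave 1022, 1099 and 501 in them. Of the 268 genes 26 to 167 remained past the threshold without a single array. None changed sign, but the groups of all 268 do not overlap, so leaving out an array could not change a sign. The 195 genes at least 2-fold became 125 without a filter, 473 with the block and 0 to 218 with arrays left out. CEBPB ranged from -2.55 to -2.15 and STAT3 from -1.74 to -1.44 with arrays left out. Without both arrays of number 1, 2 or 3, adjusted p was 0.087, 0.029 and 0.14 for CEBPB and 0.093, 0.054 and 0.20 for STAT3. The 9 lists became 2 by fry (3 with the block, adding G1/S genes) and 0 with an estimated correlation, where 2 of 23 had an unadjusted p under 0.05, and 4 to 13 with arrays left out. The count of 103 genes 2-fold apart with STAT3 siRNA was 194 and 41 with pseudocounts of 1 and 64, 60 with 60% of genes left out, 462 against all 4 controls, and 561 and 18 at 1.5-fold and 3-fold limits. STAT3 itself was -4.44 and -3.07 with pseudocounts of 1 and 64. The 20 shared genes became 11 with a pseudocount of 64, 50 with the block, 65 at a 1.5-fold limit, 44 against all 4 controls, which then share arrays with the C/EBPβ comparison, and 0 to 24 with arrays left out. Other causes were not tested.

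Except for the GAPDH covariate below, all other settings kept these results within 1.5 times. The 16 STAT3 lists numbered 12 to 17. No call changed sign. Over all alternatives named genes kept their side of the threshold 763 times in the C/EBPβ comparison, lost it 294 times and gained it 3 times, and lists 475, 30 and 22 times. In the STAT3 comparison named genes moved beyond the replicate spread 43 of 742 times. The actin ratio as a covariate gave 324 genes and the GAPDH ratio 444. Scalings moved the median of all genes by under 0.1. Of the 10 splits of the 6 arrays 1, the real one, gave 268 genes (195 at least 2-fold), and the highest other gave 0, with 18 to 724 genes at an unadjusted p under 0.05; that is too few splits for a share under 0.05. The other splits that part all 3 pairs also gave 0. Every split but the real one mixes siRNA and control arrays, so a response to the siRNA widens its groups and lowers its count. Signals under 16 bound what low genes such as CCNE2 can show.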

Other observations

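Several list members that passed over all genes with the replicate block, but not without it, had no C/EBPβ siRNA values above. Deiodinase DIO2 and interleukin 11 (IL11) had log2 differences of 2.47 and 1.70 after C/EBPβ siRNA (adjusted p = 0.0076 and 0.0088 with the block) and were among the 4 decidualization markers that rose with it, while somatostatin (SST), HSD11B1 and BMP2 had differences of -2.68, -3.12 and -2.07. IL11 was lower on the STAT3 siRNA array, at -1.46. The TGF-beta receptor TGFBR2 and activin subunit INHBA had differences of 1.23 and 2.28 after C/EBPβ siRNA and 0.83 and 0.82 after STAT3 siRNA. The other INHBA probe set, also above the filter, had smaller differences of 0.59 after C/EBPβ siRNA and 0.38 after STAT3 siRNA. These genes were chosen after their values were seen.

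The rise of actomyosin genes after C/EBPβ siRNA was weighed against 3 technical explanations, of which the test on smooth muscle cells was chosen after the result was seen and those on RNA integrity were added after seeing the data. Mature smooth muscle cells in the siRNA cultures would bring MYH11 and DES, whose brightest probe set had a mean signal of 10.2 there. The highest signal of these probe sets on any of the 8 arrays was 13.5. No array thus shows that they detect such cells, so this test cannot exclude smooth muscle cells. For RNA integrity, the list median was 0.93 with the actin 3′/5′ ratio and 0.90 with the GAPDH ratio as a covariate, from 0.98. Both ratios differed more between replicate numbers than between groups. These covariates could therefore move the group difference little, and they do not decide on RNA integrity. Array scaling is argued against by a median of 0.96 after quantile normalization. A response to the lower C/EBPβ level and an off-target effect of the siRNA also stay open and were not told apart.

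The shared direction of both knockdowns raised the hypothesis, tested after the result was seen, that C/EBPβ siRNA acts through the lower STAT3 level alone. STAT3 siRNA, which reduced STAT3 further, would then move the same genes at least as much. In each case 198 genes were chosen by their C/EBPβ response without the pair in which the C/EBPβ change was measured. In them the STAT3 change was 0.31 of the C/EBPβ change (0.29, 0.37 and 0.28 for the 3 pairs left out), less than that hypothesis asks. All 3 ratios use the same STAT3 siRNA array and its control, so they hold no spread of the STAT3 change and cannot decide. CEBPB was also lower on that array (log2 difference -0.79), and its part in the shared direction was not tested. A partial contribution of STAT3 was not tested. The low ribosomal protein genes on the STAT3 siRNA array have a median of -0.032 after quantile normalization. That step evens out bright signals whatever the cause, so it cannot tell compression on that array from a fall of these genes. Before it the list median was -0.29. Random lists matched on expression had a median of -0.12, and so did the brightest decile of genes.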
